A study of Mus musculus with 9 samples.

How the data were processed

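The series holds 9 samples of total RNA from mouse brain of strain C57BL/6, which the design text describes as cerebella at postnatal day 5, in 3 groups of 3: wild type, SmoA2 and Smo/Smo. Each sample was measured on 1 custom Affymetrix array. The deposited values are probe set intensity, summarised by RMA per the labels, which give no version. They proved to be on a linear scale, with array medians of 91 to 95.1 and nearly equal distributions in all 9 arrays. A log2 scale had been planned for, so the log2 of each value was taken before every test. Detection calls were not used here. Probe sets of Y-linked genes in the female mice, with log2 values of 2.80 to 5.57, give an indication of the background. The sex called from Xist and Y-linked probe sets was 1 male and 2 females in wild type, and 2 males and 1 female in each mutant group. Arrays have no read depth, and their number limits the precision.

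The tables supplied with the series named the genes of the probe sets. Of 38385 probe sets, 24478 carried 1 symbol, 65 several and 13842 none. The 24478 stood for 19147 genes, of which 3958 had several probe sets. The probe set with the highest mean log2 value over all 9 arrays stood for its gene. Order along chromosomes came from GRCm38.p6 and placed 19083 genes. No probe sequences were at hand, so probe sets were not aligned again, and it is not known whether the Smo probe set matches the transgene. The SmoA1 line was not named in the sample labels, and Smo/Smo was taken as that line by elimination.

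All tests were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), in 1 model of all 9 arrays with a mean per group and no covariate. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 19147 genes, in each of 3 comparisons (SmoA2 against wild type, Smo/Smo against wild type, SmoA2 against Smo/Smo) and in the moderated F test. Errors of log2 fold changes are standard errors from this model. Sets were tested with camera of limma at its preset correlation of 0.01, adjusted over the lists within a comparison. Beside each stand the calls of single members over all genes and adjusted over the list alone, and the adjusted p with the correlation estimated for the list. The 27 lists held 550 entries, of which 467 were measured: targets and components of the Shh pathway, granule neuron progenitors, cell cycle, early postmitotic and maturing granule neurons, Purkinje cells, GABAergic interneurons, unipolar brush cells and rhombic lip, Bergmann glia and astrocytes, oligodendrocyte lineage, microglia and macrophages, endothelial and mural cells, meninges and fibroblasts, choroid plexus, erythrocytes, brainstem and midbrain, forebrain, neuronal migration and axon guidance, synaptic genes, Notch, Wnt and BMP pathways, p53 targets and apoptosis, cholesterol synthesis, immediate early and stress genes, and glycolysis and hypoxia. The lists, comparisons, tests, alternatives and the rule for named genes were chosen before the data were examined. That rule took Smo, Gli1, Ptch1 and Neurod2 in any case. It added the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap, leaving out symbols that are clone or model numbers. It also added up to 4 called members of each list with the smallest p, or 2 where none was called.

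The correlation and covariance of the mutant effects were set beside 50 simulations of unchanged groups against the same controls. Neighbouring calls were counted in windows of 100 measured genes and compared with 10000 shuffles of the calls, a permutation test. Other splits of the arrays into groups of the same sizes, 10 for each pair of groups and 100 drawn for all 3 groups, were fitted in the same way. Array weights from limma gave the lowest weight, 0.386, to SmoA2 replicate 3. The alternatives were another choice of probe set, the mean of or every probe set, a filter on low values, quantile normalization, centring on array medians, an intensity trend with robust eBayes, array weights, fits of only the groups compared, stricter thresholds, sex as a covariate, other set tests and leaving out each array. Added after the values were seen were the removal of wild type replicate 3 and SmoA2 replicate 3 together, and of the genes of chromosome 14.

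The pipeline was tested on simulated data made from these arrays, in 20 simulations with 200 changed genes. It recovered 70.7% of changes of 0.5 on the log2 scale and 97.6% of changes of 1, and 4.89% of its calls were false. With no change made, it called 0.05 genes and 0.05 lists per run on average. The simulated noise was independent between genes, so these runs do not test list calls where members are correlated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probe sets without a single gene symbol were left out of the gene tests and fitted apart. The animal codes differ in prefix between Smo/Smo and the other groups, and no block could be fitted for this.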

Results

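Gene expression was measured by array in cerebella of mice at postnatal day 5, in 3 groups of 3 mice with 1 array each. The groups were wild type, SmoA2 and Smo/Smo. Per the design text, the SmoA1 and SmoA2 lines express activated forms of Smoothened, the membrane protein that passes on the Sonic hedgehog (Shh) signal. Their transgenes use a fragment of the Neurod2 promoter active in granule neuron precursors. The labels name the third group only Smo/Smo, and it was taken as the SmoA1 line by elimination. Values were read for 38385 probe sets, of which 24478 carried a single gene symbol, and 19147 genes were tested. The median intensity of an array lay between 91 and 95.1, and the correlation between any pair of arrays, across probe sets, lay between 0.994 and 0.998. The median standard deviation of a gene within a group was 0.08 on the log2 scale in wild type, 0.11 in SmoA2 and 0.08 in Smo/Smo. SmoA2 replicate 3 had the lowest mean correlation with its own group, at 0.9952. The small number of arrays limits the precision of every value.

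The comparison of SmoA2 with wild type asked which transcripts differ at postnatal day 5 in the line that the study set out to characterise. The largest rises among genes with a full symbol included transcription factors that act in other regions of the nervous system or in other tissues. Isl1, a LIM homeodomain factor of motor and sensory neurons, rose 8.40-fold (log2 fold change 3.07 ± 0.14, SE, n = 3 per group, adjusted p = 1.065e-05). Foxa2, a factor of the floor plate, rose 6.00-fold (2.58 ± 0.26 on the log2 scale), and Pou4f1, a factor of sensory neurons, rose at least 4.57-fold (2.19 ± 0.21). Myod1, the muscle determination factor, rose 3.98-fold (1.99 ± 0.09). Sowaha rose 6.48-fold, Mgarp 4.64-fold, Adam34 at least 5.49-fold and the acute-phase gene Saa2 at least 4.26-fold. Wild type means of Pou4f1 (4.77 log2), Adam34 (3.57) and Saa2 (4.24) lay within the 2.80 to 5.57 of Y-linked probe sets in females, an indication of background, so these folds are lower bounds. The other Isl1 probe set lay within that range in all 3 groups (4.17 in wild type, 5.21 in SmoA2 and 4.65 in Smo/Smo) and was not read further. The largest fall among them was in Dmrta1, a DMRT-family transcription factor, which was 4.25-fold lower (log2 fold change -2.09 ± 0.09, adjusted p = 9.712e-06). Aldh1a2, the retinoic acid synthesis enzyme of the meninges, was 2.96-fold lower, the organic anion transporter Slc22a6 2.68-fold lower and mesothelin (Msln) at least 2.57-fold lower, with its SmoA2 mean of 5.33 also within that range. Trp73, a p53 family member, was 2.72-fold lower on the probe set used, while its other probe set gave a log2 fold change of -0.25 (adjusted p = 0.48).

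In all, 184 genes were higher and 331 lower in SmoA2 than in wild type, with 31 and 18 of them changed at least 2-fold. In each of the 515 genes, the 3 arrays of 1 group lay above all 3 of the other. Groups were separated in this way in 19.1% of all genes, against 10% by chance. The number called fell to 253 without wild type replicate 1, 234 without wild type replicate 2, 323 without wild type replicate 3 and 297 without SmoA2 replicate 1. It was 215 when wild type replicate 3 and SmoA2 replicate 3 were both left out, a choice made after the values were seen.

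Some target genes of the Shh pathway were higher in SmoA2. Of 17 measured, 8 rose and 1 fell, and 8 had no call. Adjusted over the list alone, 8 rose and 3 fell. Cdk6, a kinase of the G1 phase, rose 1.88-fold (log2 fold change 0.91 ± 0.06), and cyclin D1 (Ccnd1) rose 1.95-fold (0.96 ± 0.15). Gli1, the transcription factor that the pathway induces, rose 1.41-fold (0.50 ± 0.07, adjusted p = 0.00801), and Sfrp1, a secreted Wnt antagonist, rose 1.47-fold. Ptch1, the Shh receptor, rose 1.20-fold (0.26 ± 0.05, adjusted p = 0.0371), and of its other probe sets 1 gave 0.32 (adjusted p = 0.186) and 1 lay within the range of Y-linked probe sets in females (4.91 in wild type and 5.29 in SmoA2). The 1 target that fell was the growth factor gene Igf2 (-0.55 ± 0.11, named after its values were seen). The mean log2 fold change of the list was 0.20 and camera gave an adjusted p of 0.000988, with an adjusted p of 0.173 with an estimated correlation. As the list set no expected direction for its members, its mean is not a measure of pathway activity. The call of Ptch1 was lost in each of the 9 fits that left out 1 array (adjusted p 0.065 to 0.123), and that of Ccnd1 without wild type replicate 2 (adjusted p = 0.0501). With wild type replicate 3 and SmoA2 replicate 3 both left out, Gli1 (adjusted p = 0.0775), Sfrp1 (0.0533) and Ccnd1 (0.0553) were no longer called.

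The Smo probe set itself had a log2 fold change of -0.17 ± 0.11 (adjusted p = 0.545), and whether it matches the transgene transcript is not known. Neurod2, whose promoter drives the transgene, gave -0.17 ± 0.05 (adjusted p = 0.172). Its other probe set gave -0.30 (adjusted p = 0.0533 with every probe set tested). The list of Shh pathway components was not called (adjusted p = 0.841). Its repressor gene Gli3 fell by 0.36 on the log2 scale, a call lost in 8 of the 9 fits with 1 array left out (adjusted p up to 0.134). Among 17 granule neuron progenitor markers, 2 rose and 1 fell, and the list was not called (adjusted p = 0.591). Atoh1, the factor that granule neuron progenitors need, rose 1.77-fold (log2 fold change 0.82 ± 0.07, adjusted p = 0.000703). Among 34 cell cycle genes, E2f2 fell (-0.42 ± 0.07) and 33 had no call, with an adjusted p of 0.953 for the list. The call of E2f2 was lost without wild type replicate 1 or wild type replicate 2 (adjusted p up to 0.0633). Among 16 Notch pathway genes, 3 rose, among them the effector Hes1 (0.71 ± 0.06) and the ligand Dll3 (0.73 ± 0.11), while the list was not called (adjusted p = 0.591).

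**Figure D1:**
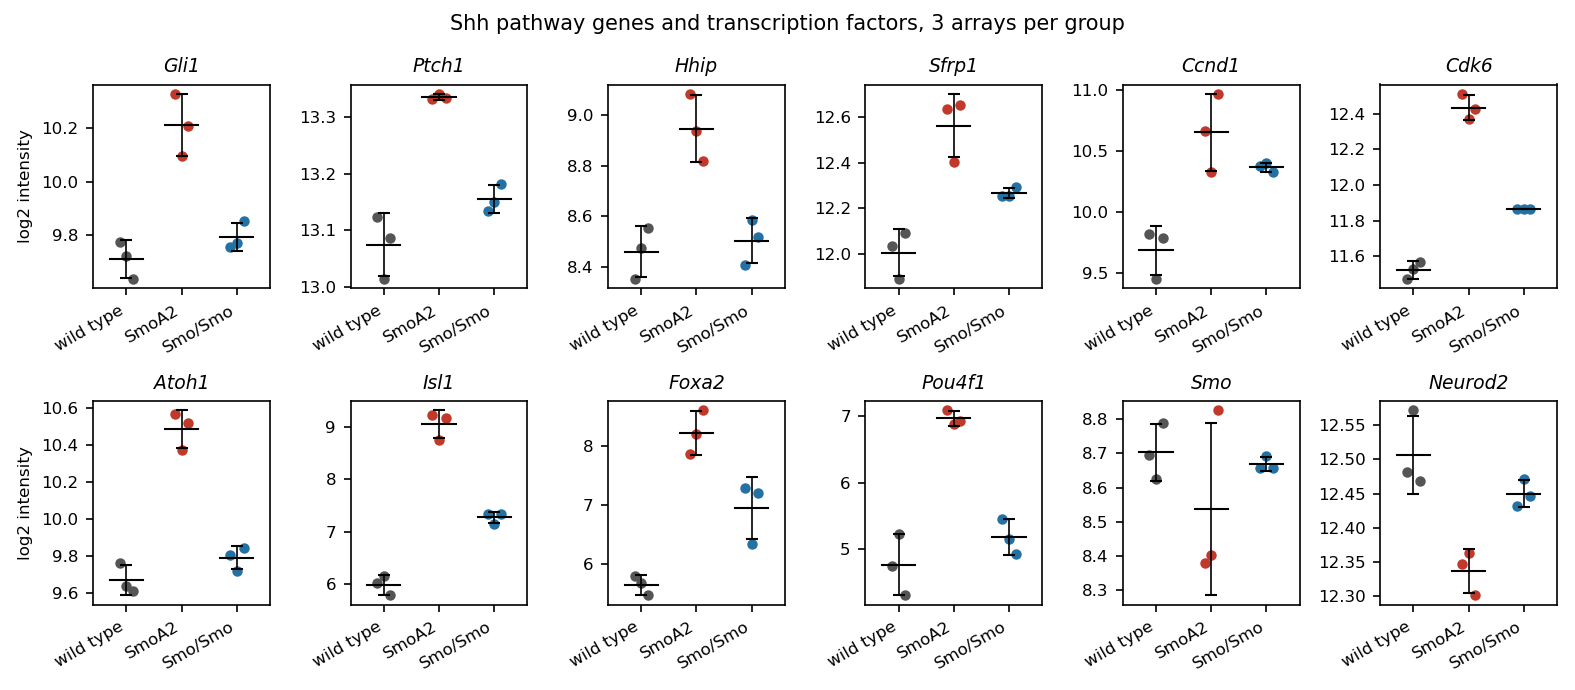
Log2 intensity (vertical axes, each with its own range) of 12 genes in wild type, SmoA2 and Smo/Smo cerebella. Points are single arrays, long bars the means and short bars 1 standard deviation. The SmoA2 arrays lie above the wild type arrays for Gli1 (log2 fold change 0.50), Atoh1 (0.82) and Isl1 (3.07), and Smo/Smo lies between them for Isl1 (1.29 above wild type).

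The lists of Purkinje cell, GABAergic interneuron, and Bergmann glia and astrocyte markers were lower in SmoA2, each with most members not called. Of 17 Purkinje cell markers, 5 fell and 1 rose, with 15 lower and 2 higher when adjusted over the list alone. Lhx5, a LIM homeodomain factor, fell by 0.66 and Dab1, the adaptor of reelin signalling, fell by 0.50 on the log2 scale. The exception was the zinc finger factor Bcl11b, which rose 3.82-fold (log2 fold change 1.93 ± 0.22, adjusted p = 0.00218). The Purkinje list gave an adjusted p of 4.857e-10 in camera, and 0.0150 with an estimated correlation. Of 13 markers of GABAergic interneurons, 5 fell and none rose, with 9 lower and 1 higher when adjusted over the list alone. Pax2, a factor of interneuron precursors, fell by 0.75, and Gad1, which makes GABA, fell by 0.51. The adjusted p of this list was 3.171e-07, and 0.0150 with an estimated correlation. Of 26 markers of Bergmann glia and astrocytes, 6 fell and none rose, with 11 lower when adjusted over the list alone. The Wnt inhibitor Wif1 fell by 1.21, the connexin gene Gjb6 by 0.95 and Gdf10, a growth factor gene of Bergmann glia, by 0.59. The adjusted p was 1.616e-05, and 0.0176 with an estimated correlation. With wild type replicate 3 and SmoA2 replicate 3 both left out, the calls of Dab1 (adjusted p = 0.0579) and Gjb6 (0.0648) ended. Choroid plexus and meningeal markers also differed in these arrays, with mean log2 fold changes of 1.37 and -0.49. Neither list call held with an estimated correlation (adjusted p = 0.342 and 0.108), and the choroid plexus mean was 0.62 without wild type replicate 3.

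Genes of the BMP pathway were lower as well. Of 17 measured, 5 fell and none rose, with 8 lower when adjusted over the list alone (adjusted p = 1.252e-05, and 0.0176 with an estimated correlation). Id3, a target of BMP signals, fell by 0.39 on the log2 scale and the ligand Bmp2 by 0.89. Leaving out single arrays ended the call of Id3 in 2 of 9 fits, those without wild type replicate 1 or 2 (adjusted p up to 0.0601). The call of Bmp2 ended in 4 of 9 fits, those without wild type replicate 1 or 2 or SmoA2 replicate 1 or 3 (adjusted p up to 0.09). Of 17 cholesterol synthesis genes, Mvd fell by 0.30 and 16 had no call. The list gave an adjusted p of 0.00072 and a mean of -0.11, with an adjusted p of 0.0374 with an estimated correlation. The call of Mvd was lost in 8 of the 9 fits (adjusted p up to 0.143). Early postmitotic granule neuron genes gave a mean of -0.10 (adjusted p = 0.00295, and 0.117 with an estimated correlation), with only Cdkn1c called among 18, at -0.39. The call of Cdkn1c was lost in 8 of 9 fits (adjusted p up to 0.151). Synaptic genes gave a mean of -0.11 (adjusted p = 0.00636, and 0.40 with an estimated correlation), with 2 of 25 lower, among them the glutamate receptor gene Gria1 (-0.66 ± 0.07). Without SmoA2 replicate 3 the synaptic list was not called (adjusted p = 0.161).

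Among lists of non-neural markers in SmoA2, camera called the meningeal and endothelial lists lower and the choroid plexus list higher, and none of these calls held with an estimated correlation. Of 19 meningeal and fibroblast markers, 10 fell and none rose, with 14 lower and 1 higher when adjusted over the list alone. Aldh1a2 fell by 1.57, Slc22a6 by 1.42 and the GABA transporter gene Slc6a13 by 1.05 on the log2 scale. The list gave a mean of -0.49 and an adjusted p of 4.698e-14, with an adjusted p of 0.108 with an estimated correlation. Of 11 choroid plexus markers, none was called in limma over all genes, 10 had an unadjusted p under 0.05 and 10 were higher when adjusted over the list alone. Their mean was 1.37, with an adjusted p of 1.058e-06, and 0.342 with an estimated correlation. Transthyretin (Ttr) had log2 intensities of 11.4, 11.3 and 4.95 in wild type replicates 1, 2 and 3, and of 11.7 to 11.9 in SmoA2. Without wild type replicate 3 the choroid plexus mean was 0.62 (adjusted p = 4.968e-13 in camera at the preset correlation, with no estimated one fitted). In that fit Ttr, Kl, Clic6, Folr1, Sostdc1 and Cldn2 were called over all genes (adjusted p 0.00694 to 0.0329). Kcnj13, Otx2, Aqp1, Kcne2 and Calml4 were not. Endothelial and mural markers gave a mean of -0.08 (adjusted p = 0.0325, and 0.371 with an estimated correlation), with Tek and Kdr lower at -0.29 and -0.30. This list was not called without wild type replicate 1 or SmoA2 replicate 1 (adjusted p up to 0.131), and single arrays ended the calls of Tek in 7 and Kdr in 9 of 9 fits (up to 0.126 and 0.125). Of the 27 lists, 2 were higher and 9 lower, and 5 of these 11 calls held with an estimated correlation.

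**Figure D2:**
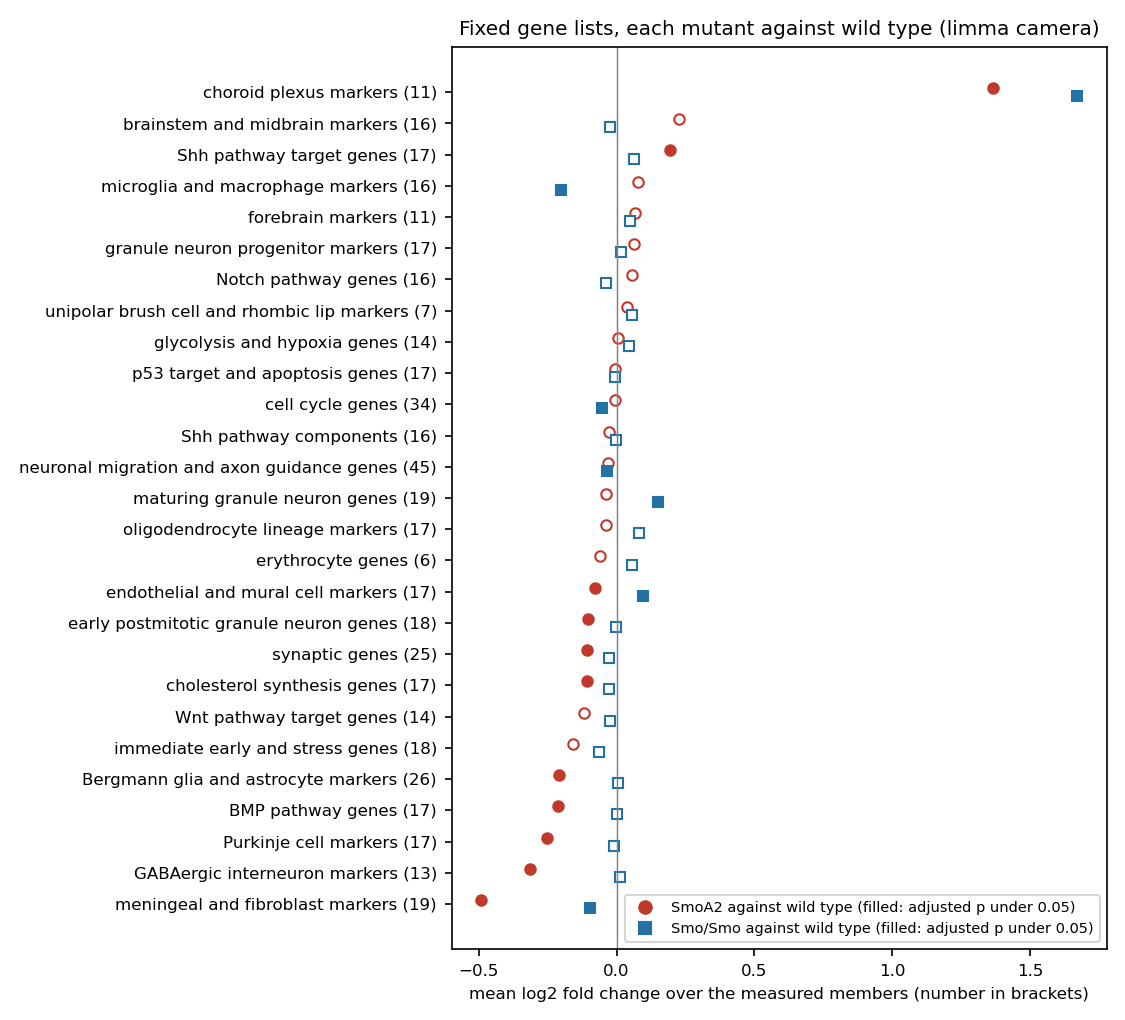
Mean log2 fold change against wild type (horizontal axis) of 27 gene lists, with the number of measured members in brackets. Circles are SmoA2, squares Smo/Smo, and filled symbols have an adjusted p under 0.05 in camera. Choroid plexus markers lie highest in both (1.37 and 1.67) and meningeal markers lowest in SmoA2 (-0.49).

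The comparison of Smo/Smo with wild type asked the same for the other mutant line, and it gave fewer differences. Ctr9, a subunit of the PAF transcription elongation complex, was 5.68-fold lower (log2 fold change -2.50 ± 0.07, n = 3 per group, adjusted p = 4.526e-07), but its other 2 probe sets gave -0.21 (adjusted p = 0.476) and -0.10 (0.876). Wdfy1 was 4.14-fold lower, with other probe sets at -1.39 (adjusted p = 0.000988) and -0.25 (0.341), and Pnma2 was 3.99-fold lower. Sowaha rose 2.99-fold and Isl1 2.45-fold (1.29 ± 0.14, adjusted p = 0.00591). Thg1l, a tRNA-modifying enzyme, rose 2.27-fold and Tmem254a 2.18-fold. Efcab7 fell by 0.84 on the log2 scale, and Impg2 by at least 0.88 to a mean of 4.74, within the range of Y-linked probe sets in females. Mid1, a ubiquitin ligase, rose 4.10-fold on the probe set used and the formin gene Diaph3 rose by 1.34 on the log2 scale. The other Mid1 probe set gave -0.09 (adjusted p = 0.977). Other Diaph3 probe sets gave -0.02 (0.979) and -0.11 (0.833), and the last lay within the range of Y-linked probe sets in females. With the mean of all probe sets of a gene, neither Mid1 (0.97, adjusted p = 0.394) nor Diaph3 (0.25, adjusted p = 0.213) was called. Mid1 was also not called without wild type replicate 2 or Smo/Smo replicate 3 (adjusted p up to 0.0691).

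In Smo/Smo, 41 genes were higher and 30 lower than in wild type, with 11 and 5 changed at least 2-fold. The 3 arrays of 1 group lay above all 3 of the other in each of these 71 genes, and in 15.9% of all genes, against 10% by chance. The number called was 25 without wild type replicate 1, 21 without wild type replicate 2, and 37, 30 and 25 without Smo/Smo replicates 1, 2 and 3. Without wild type replicate 3 it was 51, with 15 lower, and without that array and SmoA2 replicate 3 it was 38. Animal codes of the Smo/Smo mice have another prefix than those of the other groups, so an effect of their source and of the genotype cannot be told apart. Of the 71 genes, 18 lie on chromosome 14 (8 higher and 10 lower), which is 25.4% of the calls against 3.68% of the genes tested (Fisher's exact test, two-sided, p = 6.14e-11). Pnma2, Tmem254a and Diaph3, named above, are among these 18. With the genes of chromosome 14 left out, a choice made after the values were seen, 28 genes were higher and 15 lower.

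**Figure D3:**
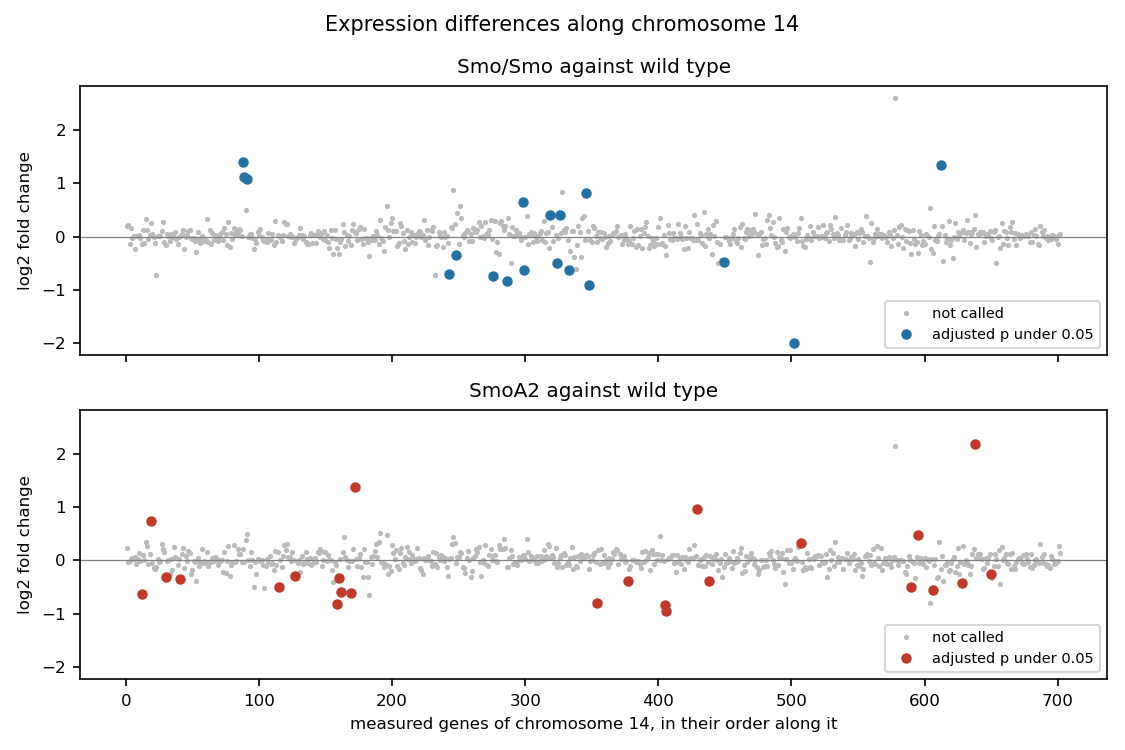
Log2 fold change against wild type (vertical axes) of the measured genes of chromosome 14 in their order along it (horizontal axis), for Smo/Smo (top) and SmoA2 (bottom). Coloured points have an adjusted p under 0.05. The 18 Smo/Smo calls include 10 within 100 neighbouring genes, some higher and some lower.

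With 1 probe set per gene, Shh pathway targets gave no call over all genes in Smo/Smo. Gli1 had a log2 fold change of 0.08 ± 0.07 (adjusted p = 0.825), Ptch1 0.08 ± 0.05 (0.741), Smo -0.03 ± 0.11 (0.962) and Neurod2 -0.06 ± 0.05 (0.839). Ccnd1 stood at 0.68 ± 0.15 (adjusted p = 0.161) and Cdk6 at 0.34 ± 0.06 (0.0530). The other Ccnd1 probe set gave 0.55 and was called when every probe set was tested (adjusted p = 0.0182). Of the 17 targets, 3 had an unadjusted p under 0.05 in limma and 2 were higher when adjusted over the list alone, and the list gave an adjusted p of 0.570. In camera 7 lists were called, and none of these calls held with an estimated correlation (adjusted p = 0.491 to 0.837). Choroid plexus markers gave a mean of 1.67 (adjusted p = 5.632e-11, and 0.491 with an estimated correlation), with 0 of 11 called over all genes, 9 at an unadjusted p under 0.05 and 9 higher when adjusted over the list alone. Without wild type replicate 3 their mean was 0.93. Ttr, Kl, Clic6, Folr1, Aqp1, Kcne2, Sostdc1 and Cldn2 were then called over all genes (adjusted p 0.00219 to 0.0467), and Kcnj13, Otx2 and Calml4 were not. Microglia and macrophage markers gave a mean of -0.20 (adjusted p = 2.591e-06, and 0.491 with an estimated correlation), with 15 of 16 members below 0, 4 at an unadjusted p under 0.05 and 0 called, over all genes or adjusted over the list alone. Maturing granule neuron genes gave a mean of 0.15 (adjusted p = 0.00854). Among them Grin2c, an NMDA receptor subunit gene, rose by 0.71 on the log2 scale, a call lost without wild type replicate 1 or 2 or Smo/Smo replicate 2 (adjusted p up to 0.0697) and with the mean of its probe sets (0.0745). The other called lists were endothelial and mural markers (mean 0.09, adjusted p = 0.0113), cell cycle genes (-0.05, 0.0308), meningeal markers (-0.10, 0.0308) and migration and axon guidance genes (-0.03, 0.0419). Of the 7, single arrays ended all but the choroid plexus and microglia calls. Those without Smo/Smo replicate 1 and wild type replicate 3 ended the maturing granule neuron call (adjusted p up to 0.0711) and the endothelial call (up to 0.151). The cell cycle call ended without wild type replicate 1 or Smo/Smo replicate 1 (up to 0.152). The meningeal call ended without wild type replicates 1 or 3 or Smo/Smo replicates 1 or 2 (up to 0.152), and the migration call also without SmoA2 replicate 1 (up to 0.289). The other 20 lists had adjusted p values of 0.211 to 0.941.

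**Figure D4:**
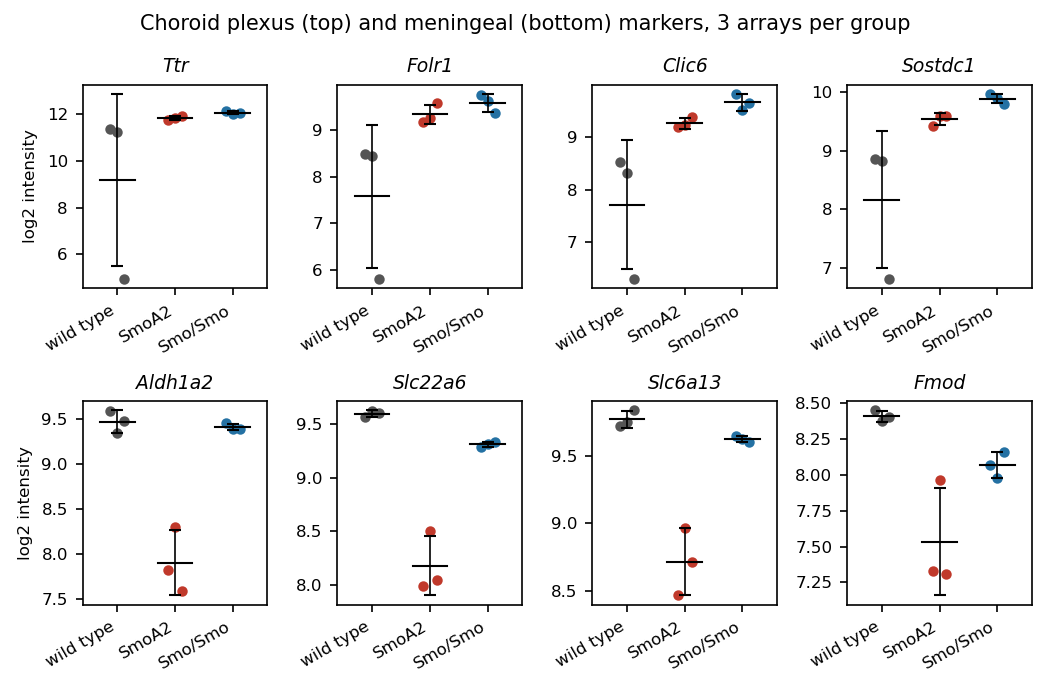
Log2 intensity (vertical axes, each with its own range) of 4 choroid plexus markers (top) and 4 meningeal markers (bottom) in wild type, SmoA2 and Smo/Smo. Points are single arrays, long bars the means and short bars 1 standard deviation. Ttr stands at 4.95 in wild type replicate 3, and Aldh1a2 is lower in the SmoA2 arrays (log2 fold change -1.57).

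The direct comparison of SmoA2 with Smo/Smo tested whether the mutant groups differ from each other. Since the animal codes of the Smo/Smo mice have another prefix, effects of source and of genotype cannot be told apart here either. Mgarp was higher in SmoA2 by 1.84 ± 0.16 and Isl1 by 1.78 ± 0.14 on the log2 scale. Adam34 was higher by at least 2.27 ± 0.12 and Pou4f1 by at least 1.78 ± 0.21, since their Smo/Smo means of 3.76 and 5.18 lay within the range of Y-linked probe sets in females. Ctr9 (2.43), Wdfy1 (2.04) and Pnma2 (2.00) were also higher on the probe sets used, and Dmrta1 (-1.82), Aldh1a2 (-1.51) and Msln (-1.46, a lower bound in size) were lower in SmoA2. The other Ctr9 probe sets gave 0.10 (adjusted p = 0.656) and 0.05 (0.906), and those of Wdfy1 1.35 (0.000684) and 0.32 (0.0816). In SmoA2 against wild type, Ctr9, Wdfy1 and Pnma2 gave only -0.08, -0.01 and 0.004, so their differences between the mutants lay in Smo/Smo. Pnma2 and Pou4f1 lie on chromosome 14. Between the mutants, 4 of 17 Shh targets were higher in SmoA2 and none lower, with 8 higher and 3 lower when adjusted over the list alone. They included Cdk6 (0.57 ± 0.06), Gas1 (0.42 ± 0.05) and Gli1 (0.42 ± 0.07, adjusted p = 0.0205), while Ptch1 gave 0.18 ± 0.05 (0.140), Smo -0.13 ± 0.11 (0.686) and Neurod2 -0.11 ± 0.05 (0.401). The other Neurod2 probe set gave -0.29 (adjusted p = 0.0655 with every probe set tested). The target list gave a mean of 0.13 and an adjusted p of 0.000842, with an adjusted p of 0.153 with an estimated correlation. The list set no expected direction for its members, Gas1 among them, so its mean is not a measure of pathway activity. Atoh1 was higher by 0.70 ± 0.07 (adjusted p = 0.00189) and Bcl11b by 1.61 ± 0.22. Purkinje (6 of 17 lower and 1 higher), GABAergic interneuron (5 of 13 lower), Bergmann glia and astrocyte (5 of 26 lower) and BMP pathway (1 of 17 lower) lists were lower in SmoA2, with adjusted p values of 0.00923 to 0.0144 with an estimated correlation. Adjusted over the list alone, 14, 10, 8 and 9 of their members were lower. Camera also called meningeal (mean -0.39, 6 of 19 lower) and endothelial and mural markers (-0.17, 3 of 17 lower) as lower, and microglia and macrophage markers (0.28, 3 of 16 higher and 1 lower) as higher. These 3 calls did not hold with an estimated correlation (adjusted p = 0.144, 0.0884 and 0.182). The call of Gli1 was lost without SmoA2 replicate 1 and without each of the 3 Smo/Smo arrays (adjusted p up to 0.089), with only the groups compared in the fit (0.0653), and without wild type replicate 3 and SmoA2 replicate 3 (0.0706).

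Between the mutants, 196 genes were higher and 294 lower in SmoA2, with 28 and 19 changed at least 2-fold, and 18.2% of all genes had no overlap between the groups, against 10% by chance. The number called was 247 without SmoA2 replicate 1, and 219, 170 and 202 without Smo/Smo replicates 1, 2 and 3. Those higher were 125 without wild type replicate 1 and 126 without wild type replicate 2, and 296 genes were called without wild type replicate 3 and SmoA2 replicate 3. The F test over all 3 groups called 553 genes. It called 329 without wild type replicate 1 or wild type replicate 2, 268 without SmoA2 replicate 1, and 345, 312 and 339 without Smo/Smo replicates 1, 2 and 3, and 270 without the pair of wild type replicate 3 and SmoA2 replicate 3.

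To ask whether the mutants changed the same genes, their effects against wild type were compared. In both, 17 genes were higher and 3 lower, and none was called in opposite directions. Of the 20 shared genes, 15 had the larger change in SmoA2, and 8 of the 20 also differed between the mutants, among them Isl1, Sowaha, Lama5, a laminin chain gene, and Lrig3. Lama5 was higher by 1.81 in SmoA2 and 0.72 in Smo/Smo on the log2 scale (both named after their values were seen). The 3 genes lower in both were Fgf15, Clec4a1 and Ptger3, also named after their values were seen. Fgf15 gave -0.51 in SmoA2 and -0.75 in Smo/Smo. Across all genes, which are not independent replicates, the effects had a correlation of 0.515, against a mean of 0.495 (SD 0.041) in 50 simulations with unchanged groups and shared controls. Their covariance was 0.0175, against a mean of 0.00648 (SD 0.000689) and a highest value of 0.0077 in the simulations. The simulated noise was independent between genes. It held no deviation of many genes in 1 array, such as that of choroid plexus markers in wild type replicate 3. The higher covariance can therefore not be credited to shared mutant effects. Both effects use the same wild type arrays, which cannot be split with 3 of them, so how many genes would be shared by chance is not known. The number of shared higher genes was 5 without wild type replicate 1, 3 without wild type replicate 2 and 11 without SmoA2 replicate 2. It was 4, 5 and 5 without Smo/Smo replicates 1, 2 and 3. The number of shared lower genes was 0 without wild type replicate 1, wild type replicate 2, Smo/Smo replicate 3, or the pair of wild type replicate 3 and SmoA2 replicate 3. It was 1 without SmoA2 replicate 1, SmoA2 replicate 3 or Smo/Smo replicate 2.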

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

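The tests of clustering along the chromosomes, of brainstem or midbrain tissue and of forebrain tissue, and the fits without chromosome 14, were chosen only after the result was seen.

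SmoA2 and Smo/Smo were measured against the same controls, and results whose effects differed between them in the direct test drew attention. In that test 196 genes were higher and 294 lower in SmoA2, and effects of mouse source and of genotype cannot be told apart. Among the lists, the mean log2 difference of SmoA2 from Smo/Smo was -0.39 for meningeal markers, -0.25 for Purkinje cell markers, -0.32 for GABAergic interneuron markers and -0.21 for Bergmann glia and astrocyte markers. It was 0.28 for microglia and macrophage markers, -0.21 for BMP pathway genes, -0.17 for endothelial and mural markers and 0.13 for Shh targets. It was -0.19 for maturing granule neuron genes, -0.0823 for cholesterol synthesis genes, -0.10 for early postmitotic granule neuron genes and 0.0491 for cell cycle genes. The cell cycle call was lost without SmoA2 replicates 1 or 3 or Smo/Smo replicate 1 (adjusted p up to 0.326). The early granule neuron call was lost without SmoA2 replicate 2 or Smo/Smo replicate 3 (adjusted p up to 0.0667). Of these 12 list calls, 4 held with an estimated correlation, those of Purkinje cell, GABAergic interneuron, Bergmann glia and astrocyte, and BMP pathway lists. Those of maturing granule neuron (adjusted p = 0.182), cholesterol synthesis (0.0884), early postmitotic granule neuron (0.153) and cell cycle genes (0.641) were among the calls that did not hold.

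Single genes that differed in the same test, by log2 fold change of SmoA2 against Smo/Smo, were Gli1 (0.42), Ctr9 (2.43), Adam34 (2.27), Wdfy1 (2.04), Pnma2 (2.00), Mir100hg (1.95), Mgarp (1.84), Pou4f1 (1.78) and Isl1 (1.78). Lower in SmoA2 were Crabp1 (-3.04), Mid1 (-2.11), Dmrta1 (-1.82), Aldh1a2 (-1.51), Diaph3 (-1.49), Msln (-1.46), Plscr2 (-1.37) and Cnmd (-1.34). Of these single genes, Pnma2, Pou4f1, Diaph3 and Cnmd lie on chromosome 14. Leaving out single arrays ended the call of Crabp1 in 7 of 9 fits (adjusted p up to 0.148), that of Mir100hg in 8 (up to 0.139) and that of Gli1 in 4 (up to 0.089). With the mean of all probe sets of a gene, Mid1 (-1.12, adjusted p = 0.119) and Diaph3 (-0.22, adjusted p = 0.136) were not called. The other Mid1 probe set gave -0.12 (0.948), and the other well-measured Diaph3 probe sets gave 0.10 (0.815) and 0.21 (0.429). Other probe sets gave 0.10 (adjusted p = 0.656) and 0.05 (0.906) for Ctr9, 1.35 (0.000684) and 0.32 (0.0816) for Wdfy1, and at least 0.64 (0.163) for Mir100hg, with a Smo/Smo mean of 5.40. The lower group mean lay within the 2.80 to 5.57 log2 of Y-linked probe sets in females for that probe set, Adam34 (3.76), Pou4f1 (5.18), Msln (5.33) and Cnmd (5.41), so these differences are lower bounds, and both means did for Plscr2 (3.74 and 5.11). Against wild type, SmoA2 gave -0.08 for Ctr9, -0.01 for Wdfy1, 0.004 for Pnma2 and -0.10 for Mir100hg. It gave 0.09 for Crabp1, -0.07 for Mid1, -0.15 for Diaph3 and 0.05 for Plscr2. For these genes the difference between the mutants lay in Smo/Smo. Smo/Smo against wild type gave 3.13 for Crabp1 (adjusted p = 0.125 with every probe set tested) and -2.05 for Mir100hg (0.0904). Signals also came from the 13907 probe sets without a single gene symbol, which the comparisons above did not use. Of these, 122 were called in SmoA2 against wild type and 30 in Smo/Smo against wild type.

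The Smo/Smo calls were densest in 1 stretch of chromosome 14. There, 10 genes from Tmem260 to Acin1 were called among 100 neighbours (3 higher and 7 lower), against 0.372 for an even spread. The chromosome held 18 calls in all, so calls also lay outside this stretch, and the median below does not cover them. Chance clustering is argued against, since the fullest window in 10000 shuffles held 8 calls (permutation p = 1e-04, the smallest they can give). A shift of the whole stretch, as from an extra or missing copy, is also argued against, since the median log2 fold change of its 36 well-measured genes was 0.0749 (95% bootstrap interval -0.0327 to 0.137). Sequence differences under single probe sets could give changes in both directions, and they stay open because only 2 other probe sets of these genes could be read, of which 1 (50%) moved the same way, beside 1 of 4 (25%) for all Smo/Smo calls of chromosome 14, 3 of 6 on other chromosomes and 59 of 69 (85.5%) for the SmoA2 calls. The transgene, its place of insertion and a possible other source of the Smo/Smo mice, for which there is only their code prefix, also stay open, as untested.

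Isl1, Foxa2 and Pou4f1, which act in other regions of the nervous system, and Bcl11b, a member of the Purkinje cell list, were among the strongest rises in SmoA2. Tissue from brainstem or midbrain could carry such transcripts, but only Slc17a6 of that list was well measured (log2 fold change -0.0754), and the list was not called (adjusted p = 0.203, 0 of 16 called), though 12 of 16 members lay above 0 (mean 0.23, 1 higher when adjusted over the list alone) and Hoxb2 stood at 0.53 (adjusted p = 0.0583, groups not overlapping) with both means (3.45 and 3.98) within the range of Y-linked probe sets in females. For forebrain tissue only Bcl11a and Neurod6 were well measured (median -0.149), and that list was not called either (adjusted p = 0.780, with Fezf2 the single gene called of 11). With so few members, neither source can be told apart from a change within the cerebellum. An effect of the SmoA2 transgene on these genes stays open, as a biological hypothesis that these arrays do not test.

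In camera, choroid plexus markers were higher in both mutants (0 of 11 called over all genes in either) and meningeal markers lower in SmoA2 (10 of 19 called), but no such list call held with an estimated correlation (adjusted p = 0.342, 0.491 and 0.108). Loss of choroid plexus from wild type replicate 3, where Ttr stood at 4.95 against 11.3 and 11.4 in the other wild type arrays, is argued against as the whole cause. Without that array the list was still called in both mutants at the preset correlation of 0.01 (the larger adjusted p was 4.968e-13). Its mean fell from 1.37 to 0.62 in SmoA2 and from 1.67 to 0.93 in Smo/Smo. No fit without that array estimated the correlation, which was 0.787 with all arrays, so this p does not weigh against that cause. The argument rests on single members set against the remaining wild type arrays, the same ones for both mutants. Without wild type replicate 3, Ttr, Kl, Clic6, Folr1, Sostdc1 and Cldn2 were called over all genes in both mutants. Aqp1 and Kcne2 were called only in Smo/Smo, and Kcnj13, Otx2 and Calml4 in neither. If the meningeal fall is real, less meningeal tissue on the SmoA2 cerebella would lower markers made only by meninges by a common amount. Of the list, 68.4% (13 of 19) lay under -0.3, and the 95% intervals of Lum, Mgp, Islr and Zic4 lay wholly above it. By the rule set beforehand, that many such intervals argue against a fall by a common amount, and Lum stood at 0.38 (95% interval 0.07 to 0.69). Members also made by other cells would fall less, as granule cells also express Zic4, and the rule made no allowance for this. The test therefore cannot decide whether tissue loss is the whole cause. How much of each tissue was dissected, and an effect of the transgenes on it, may both contribute and stay open.

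Other splits of the arrays were fitted for each count. For each pair of groups the 10 splits are too few for a share under 0.05, with real counts of 515, 71 and 490 genes, 1 split of the 10 reaching each of them and 0 genes as the highest of the others. For the F test, 1 of 100 splits, the real one with 553 genes, gave as many, and the highest of the others gave 223. This argues against chance for that count, though 1 of 100 is the smallest share these splits can give. It does not tell an effect of genotype from one of a possible other source of the Smo/Smo mice.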

How the results depend on the processing

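The fits without wild type replicate 3 and SmoA2 replicate 3 together, and those without chromosome 14, were chosen after the values were seen. No named gene or list that was called in the main fit or in an alternative changed its direction between them. Direction was not compared where neither fit gave a call, and counts were compared only in size. For the named genes of SmoA2 against wild type, 1424 of 1708 alternative values kept their side of the threshold, 266 lost and 18 gained a call. For Smo/Smo against wild type these were 1537 of 1615, 61 and 17, and for SmoA2 against Smo/Smo 1424 of 1730, 288 and 18. Counts that moved by over 1.5 times are given as higher and lower, and the cause was not tested unless stated. SmoA2 against wild type (184 and 331) gave 102 and 133 with only the groups compared in the fit (fewer arrays), 85 and 102 at an adjusted p under 0.01, and 31 and 18 at a fold of 2 or more. It gave 499 lower with an intensity trend and robust eBayes, and 101 and 114 without the doubted pair of arrays. Smo/Smo against wild type (41 and 30) gave 92 and 70 with array weights, 23 and 19 with only the groups compared, 11 and 8 at 0.01, 11 and 5 at a fold of 2, and 27 and 15 with sex as a covariate. It gave 62 higher with the intensity trend, 27 and 11 without the doubted pair, and 15 lower without chromosome 14. SmoA2 against Smo/Smo (196 and 294) gave 331 and 493 without genes below the median level (fewer genes tested), 316 and 479 with the intensity trend, 99 and 132 with only the groups compared, 71 and 71 at 0.01, and 28 and 19 at a fold of 2. It gave 128 higher with sex as a covariate, and 125 and 171 without the doubted pair. The F test (553) gave 895 without low genes, 933 with the intensity trend, 185 at 0.01 and 270 without the doubted pair. Leaving out 1 array gave 109 to 170 higher and 125 to 293 lower for SmoA2 against wild type, 12 to 40 and 8 to 28 for Smo/Smo, 79 to 182 and 91 to 285 for SmoA2 against Smo/Smo, and 268 to 476 in the F test. Totals without wild type replicates 1, 2 and 3 were 253, 234 and 323 for SmoA2 (297 without SmoA2 replicate 1) and 25, 21 and 51 for Smo/Smo (37, 30 and 25 without Smo/Smo replicates 1, 2 and 3). Between mutants they were 247 without SmoA2 replicate 1, 330 and 327 without wild type replicates 1 and 2, and 219, 170 and 202 without Smo/Smo replicates 1, 2 and 3. In the F test they were 329 and 329 without wild type replicates 1 and 2, 268 without SmoA2 replicate 1 and 345, 312 and 339 without Smo/Smo replicates 1, 2 and 3. Shh targets kept a mean of 0.17 to 0.21 for SmoA2 against wild type (0.20 with an estimated correlation and on ranks, adjusted p 0.173 and 0.0856, both no longer called), 0.04 to 0.08 for Smo/Smo and 0.11 to 0.15 between mutants (0.13 with an estimated correlation, adjusted p 0.153, no longer called). Lists called higher and lower were 2 and 9 for SmoA2 against wild type, with 0 and 5 under an estimated correlation, 1 higher by fry and 1 on ranks, and 2 to 3 and 8 to 11 without 1 array. For Smo/Smo they were 3 and 4, with 0 and 0 under an estimated correlation and by fry, 1 lower without low genes and 1 with quantile normalization, 1 higher without the doubted pair, and 1 to 3 and 1 to 4 without 1 array (1 higher without wild type replicate 3 or Smo/Smo replicate 1, 1 lower without Smo/Smo replicate 1, 2 without wild type replicate 1 or Smo/Smo replicate 2). Between mutants they were 3 and 9, with 0 and 4 under an estimated correlation, and 3 to 4 and 8 to 10 without 1 array. The correlation of the effects (0.515) was 0.406 over genes of the F test and 0.444 to 0.596 without 1 array. Genes shared as higher (17) numbered 28 without low genes and 3 to 20 without 1 array (5 and 3 without wild type replicates 1 and 2, 11 without SmoA2 replicate 2, and 4, 5 and 5 without Smo/Smo replicates 1, 2 and 3), and shared as lower (3) 0 without the doubted pair and 0 to 4 without 1 array (0 without wild type replicates 1 or 2 or Smo/Smo replicate 3, and 1 without SmoA2 replicates 1 or 3 or Smo/Smo replicate 2). Not run were the removal of cross-hybridising probe sets, since no name carries their suffixes, and, for the F test, a fold threshold and a fit of only the groups compared. Detection calls were not used here, and Y-linked probe sets in females (2.80 to 5.57 log2) are the only indication of background, within which the wild type means of Adam34 (3.57), Saa2 (4.24) and Pou4f1 (4.77) lay.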

Other observations

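The search for neighbouring calls in SmoA2, against wild type and against Smo/Smo, and the fits without wild type replicate 3 and SmoA2 replicate 3, were chosen after the values were seen. Outside the groups described above, single genes of other lists also changed in SmoA2 against wild type. Hk2, a hexokinase, rose 1.91-fold (log2 fold change 0.93 ± 0.09, adjusted p = 0.00114) while Ndrg1 fell by 0.50 and Car9, a carbonic anhydrase, by at least 0.69 to a mean of 5.38, within the 2.80 to 5.57 of Y-linked probe sets in females. With 1 of 14 higher and 2 lower, the glycolysis and hypoxia list was not called (adjusted p = 0.847). The calls of Car9 and Ndrg1 were lost without wild type replicate 2 or SmoA2 replicate 1, and that of Ndrg1 also without wild type replicate 1 (adjusted p up to 0.0639 and 0.0687). With the mean of its probe sets Ndrg1 stood at -0.32 (adjusted p = 0.154). Mrc1, a receptor of border macrophages, fell by 0.72, the only call among 16 microglia and macrophage markers (adjusted p of the list 0.204). Fezf2, a forebrain factor, rose by at least 0.74 from a wild type mean of 5.51, also within that range, and the heat shock gene Hspa1b fell by 0.62, the only call among 18 immediate early and stress genes (0.0510). Of 45 migration and axon guidance genes, 2 rose and 4 fell (0.0510), among them Dab1 at -0.50 and the chemokine gene Cxcl12 at -0.46. With wild type replicate 3 and SmoA2 replicate 3 both left out, Dab1 (adjusted p = 0.0579) and Cxcl12 (0.0554) were not called.

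Lists without a call in SmoA2 against wild type also included Wnt targets (2 of 14 lower, adjusted p = 0.208), with Wif1 at -1.21, and maturing granule neuron genes (1 of 19 higher, 0.591), with Grin2c at 0.64. Of 7 unipolar brush cell and rhombic lip markers, Tbr1 fell by 0.62 (0.757), a call lost in 4 of 9 fits with 1 array left out, those without wild type replicates 2 or 3 or SmoA2 replicates 1 or 3 (adjusted p up to 0.0973), and also with array weights, sex as a covariate, only the groups compared, or wild type replicate 3 and SmoA2 replicate 3 left out (0.0530 to 0.124). No member was called in limma among 17 oligodendrocyte lineage markers (0.591), 6 erythrocyte genes (0.780) and 17 p53 targets (0.847), where 4, 0 and 5 had an unadjusted p under 0.05. Adjusted over the list alone, 3 oligodendrocyte markers were higher and 1 lower, and Bcas1 stood at 0.30 ± 0.08 (adjusted p = 0.0839). For Notch, Shh component, and glycolysis and hypoxia genes the mean and the median differed in sign, and none of these lists was called.

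In the direct comparison of the mutants, microglial genes stood higher in SmoA2 than in Smo/Smo, with 3 of 16 members higher and 1 lower, and 10 higher when adjusted over the list alone. Against wild type the mean of the list was 0.08 in SmoA2 (adjusted p = 0.204 in camera) and -0.20 in Smo/Smo, so most of the difference lay in Smo/Smo. P2ry12, a receptor of resting microglia, was 1.74-fold higher (log2 fold change 0.80 ± 0.12, adjusted p = 0.01), a call lost without Smo/Smo replicate 2 (0.0518). Mrc1 was lower, at -0.64 ± 0.07. The list gave an adjusted p of 3.919e-06, with an adjusted p of 0.182 with an estimated correlation. Hes1 was higher by 0.48 ± 0.06 and Hk2 by 0.92 ± 0.09, and Gria1 lower at -0.68 ± 0.07.

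In SmoA2 against wild type the fullest window of 100 neighbouring genes held 10 calls, on chromosome 13, and 9 was the median of the fullest windows of 10000 shuffles (permutation p = 0.3). In SmoA2 against Smo/Smo it held 16 calls, from Ttc5 to Cpne6 on chromosome 14 (9 higher and 7 lower), against a highest of 15 in the shuffles (permutation p = 1e-04). Chromosome 14 held 44 of the 488 placed calls of that comparison, or 9.02% against 3.68% of the genes (Fisher's exact test, two-sided, p = 5.26e-08).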
